A study of Mus musculus with 4 samples.

How the data were processed

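Droplet-based single-cell RNA-seq (10x Genomics 3' chemistry) was run on lymph node cells of Apoe-deficient C57BL/6 mice, a strain that develops atherosclerosis. The 4 libraries formed 4 groups of 1 library each, by genotype at Ccl17 and by setting. Het mice carried 1 intact Ccl17 allele and 1 allele with an enhanced green fluorescent protein (EGFP) reporter in its place, and Hom mice carried the reporter on both alleles. In the chow setting, nodes from several sites were pooled, B cells were depleted on CD19 beads and live CD45+ CD11c+ CD3- CD19- cells were sorted, from 8 Het and 6 Hom mice. In the western diet setting, para-aortic nodes were taken after 6 weeks of diet and live CD45+ CD19- MHC class II+ cells were sorted, from 7 Het and 10 Hom mice. The settings therefore differed in diet, nodes and sort gate at once, and were read separately.

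The deposited values were raw UMI counts per gene and cell, as sparse matrices of 31054 features that included an EGFP entry. Per the file headers, the matrices were written by Cell Ranger 3.0.1 for the chow libraries and 3.1.0 for the western diet libraries, so the counting software differed between settings but not within either pair. The submitters' processing notes name Cell Ranger 3.0.1, Seurat 3.2.3 and the mm10 build without their roles. No cell annotation was used from the authors. Gene coordinates were taken from the GENCODE M21 annotation of GRCm38, the same assembly as mm10.

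Cells with under 500 detected genes or with at least 10% mitochondrial UMIs were left out. Doublets were ranked per library with a Scrublet-type score (scanpy, expected rate 0.06), and the highest 0.8% per 1000 recovered cells were removed. Of 8990 and 9935 deposited cells in the chow Het and Hom libraries, 7992 and 8270 were kept. Of 6416 and 6908 in the western diet Het and Hom libraries, 5810 and 6353 were kept. The mitochondrial filter removed 241 and 521 chow cells but 10 and 16 western diet cells.

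The cells of a setting were clustered together without batch correction, since library and genotype coincided. Counts were scaled to 10000 per cell and logged, 2000 variable genes gave 30 principal components, 20 neighbours were linked per cell and Leiden clustering was run at resolution 1. The 12 focus genes (Ccl17, Ccl22, Cx3cl1, Ccl3, Ccl4, Ccl5, Ccr1, Ccr4, Ccr5, Ccr7, Ccr8 and Apoe), the stress response, sex-linked, mitochondrial and ribosomal protein genes, the genes beside Ccl17, haemoglobin and antigen receptor genes were kept out of the variable genes. A cluster was called X-like from 20 fixed marker sets when at least 3 markers were detected, the score was at least 1 and exceeded the next by 0.5, and the 10 leading genes did not go against the name. The scoring thresholds were set after the clusters were seen. Other clusters stayed unnamed.

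Raw counts were summed per library and class and expressed as CPM (counts scaled to a fixed total per class), and log2 ratios of Hom over Het were computed after adding 5 CPM. Classes with at least 200 cells in both libraries of a setting were compared gene by gene. With 1 library per group there was no replicate check and no test, p-value or standard error. Sums carry exact Poisson 95% intervals, shares exact binomial (Clopper-Pearson) 95% intervals, and ratios of sums or shares conditional exact 95% intervals, all of which cover counting error only. A count of 0 was given a limit of 3 counts. To compare shares of cells with a UMI, cells were thinned to 2000 UMIs and shallower cells were left out.

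Genes were named by a fixed rule of size: among genes with a mean of at least 50 CPM and at least 20 UMIs in the higher library, the 12 with the highest and the 12 with the lowest log2 ratio per class, without mitochondrial, ribosomal, antigen receptor and unnamed gene models. Focus genes (not in every class, and without Apoe), sex-linked genes and up to 4 members of a described gene list were named as well. Genes with a same-signed ratio of at least 1.5-fold in both settings came first. For 27 fixed gene lists, the median log2 ratio over members of at least 5 CPM was set against 10000 random lists of the same size matched on mean expression (drawn within 100 genes of similar level), and its percentile is given as a description of these libraries. The grouping, the comparisons, the gene lists, the markers, the naming rule for genes and most alternatives were fixed before the data were examined.

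The gene and list steps were tested on simulated counts, drawn as Poisson sums per class. Interval coverage near 95% was therefore built in, and the simulation held no spread between cells. In the chow Ccr7+ DC-like class (2445 genes), 100 genes altered 2-fold were recovered at median log2 ratios of 0.96 and -0.97, 100 genes altered 1.5-fold at 0.55 and -0.59, and the intervals held the true ratio for 95.5% of genes. A list shifted by 0.5 was found at 0.44 in that class, and at 0.47 in the chow NK-like class (3143 genes) and in the western diet T-like class (2319 genes).

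The alternatives covered the cell filters, doublet removal, clustering resolution, clustering of the 4 libraries together, thinning, equal weight per cell, median-of-ratios scaling, the pseudocount and the minimum levels. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with seed 1.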

Results

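Lymph node cells of Apoe-deficient mice with 1 or no intact copy of Ccl17, a chemokine gene of dendritic cells (DCs), were profiled in 2 settings, with 1 library per genotype in each. The chow libraries held 8990 Het and 9935 Hom cells with 64693598 and 63244656 UMIs, and medians of 5927 and 5234 UMIs per cell. The western diet libraries held 6416 Het and 6908 Hom cells with 40193572 and 45184863 UMIs, and medians of 5266 and 5419.5 per cell. No difference below has a replicate check, because each group was 1 library of pooled mice, and intervals (95%) cover counting error only. Hom is compared with Het throughout.

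The targeted gene was examined first, to check the genotype labels. Ccl17, which encodes a ligand of the receptor Ccr4, was nearly absent from the chow Hom library, and its transcripts in the Het library lay mostly in Ccr7+ DC-like cells, the migratory DCs of lymph nodes. In that class Ccl17 measured 59.3 CPM (53.5 to 65.5) in Het and 0.904 CPM (0.390 to 1.78) in Hom, from 384 and 8 UMIs, a ratio of 0.0152 (0.00653 to 0.0303). The EGFP reporter was higher in Hom, at 56.2 against 36.9 CPM, a ratio of 1.52 (1.30 to 1.78), but the clusters of the class differed, from 0.281 (0.129 to 0.580) in cluster 11 and 0.960 (0.781 to 1.18) in cluster 6 to 4.46 (2.49 to 8.47) in cluster 9. Over all deposited chow cells, Ccl17 UMIs numbered 511 in Het and 12 in Hom, and EGFP UMIs 351 and 629.

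Ccl17 (ENSMUSG00000031780) lies on chromosome 8 at 94810453 to 94812036 of GRCm38, on the plus strand, with 3 exons. The labels do not say which part of the gene the reporter replaces, so the position of the counted 3' ends relative to it is open. A Ccl17 UMI was seen in 11.8% of Ccr7+ DC-like cells in Het (117 of 990) and 0.460% in Hom (8 of 1739), at median depths of 5559.5 and 4464 UMIs. In NK-like cells, which should lack the gene, the shares were 0.104% (3 of 2883) and 0 of 1975, which allows up to 0.152%, at median depths of 5776 and 5439. After thinning to 2000 UMIs, 5.33% (51 of 957) and 0.317% (5 of 1577) of Ccr7+ DC-like cells had a Ccl17 UMI, with 33 and 162 shallower cells left out, and no NK-like cell had one. Classical monocyte-like cells held 22 Ccl17 UMIs in Het and 1 in Hom, a ratio of 0.0697 (0.00169 to 0.431), but 2 cells carried all of those in Het.

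Ccl22, the other Ccr4 ligand and a neighbour of Ccl17 on chromosome 8 (94745590 to 94751699, 4 exons), was lower in Hom Ccr7+ DC-like cells, at 229 against 304 CPM, a ratio of 0.753 (0.707 to 0.802). The ratio was 0.285 (0.234 to 0.347) in cluster 11 of that class and was 0.763 or more in its other clusters. Cx3cl1, the ligand of Cx3cr1 and also a neighbour (94772009 to 94782427, 4 exons), had 34 UMIs in Het and 22 in Hom, a ratio of 0.473 (0.264 to 0.833). The genes beside Ccl17 as a list had a median log2 ratio of -0.16 in this class, with 1 of 13 members higher, at percentile 30.1 of matched random lists. In the western diet libraries Ccl17 had 3 UMIs in Het and 5 in Hom (ratio 1.48, 0.288 to 9.55) and EGFP 11 and 22 (1.78, 0.827 to 4.06), so the genotype labels of that pair could not be checked from the target.

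**Figure D1:**
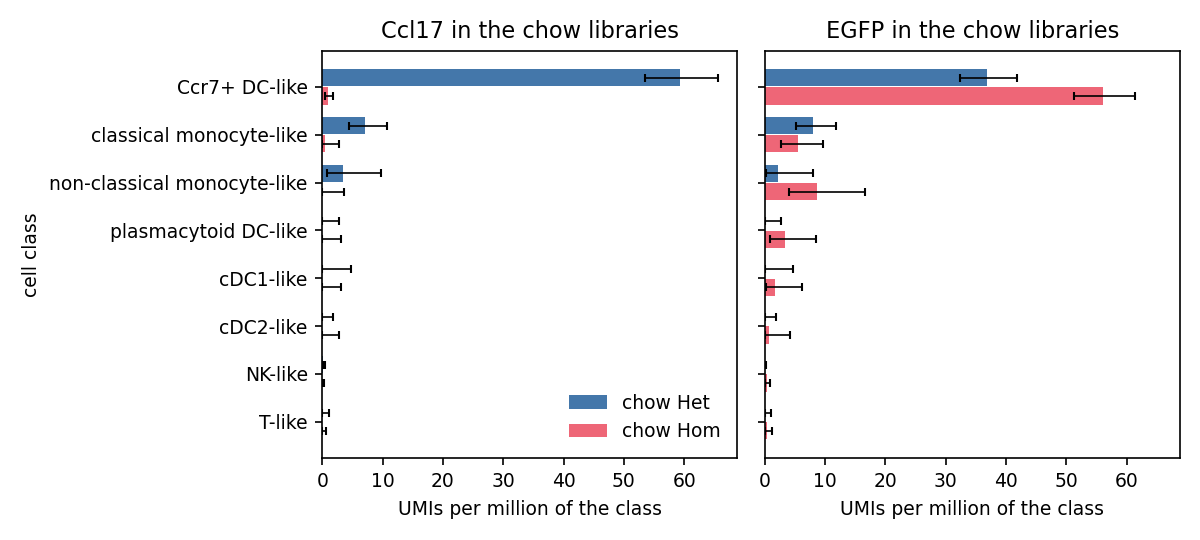
Ccl17 and EGFP in CPM of selected cell classes in the chow Het and Hom libraries, with error bars for the exact Poisson 95% intervals, which cover counting error only. In chow Ccr7+ DC-like cells Ccl17 was 59.3 CPM in Het and 0.904 in Hom, while EGFP was 36.9 and 56.2.

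In the chow pair, NK-like cells took a smaller share of the Hom library and Ccr7+ DC-like and T-like cells a larger share. NK-like cells, cytotoxic innate lymphocytes, made up 36.1% of Het and 23.9% of Hom cells, a ratio of 0.662 (0.625 to 0.701). Ccr7+ DC-like cells made up 12.4% and 21.0% (1.70, 1.57 to 1.84). T-like cells made up 5.44% and 10.1% (1.86, 1.65 to 2.09), although CD3+ cells had been gated out. B-like cells, removed by both beads and gate, made up 0.551% and 0.0726%.

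Smaller myeloid classes of the chow pair went both ways. Shares in Het and Hom were 1.19% and 1.64% for cDC1-like cells, the cross-presenting DCs, and 2.63% and 2.12% for cDC2-like cells, the DCs that mainly prime CD4+ T cells. Classical monocyte-like cells took 3.45% and 2.32% (0.672, 0.556 to 0.811), non-classical monocyte-like cells 2.03% and 2.53%, and plasmacytoid DC-like cells, interferon producers, 2.01% and 1.75%. Unnamed clusters held 34.0% and 34.5% of cells. The CD11c+ CD3- CD19- gate and the B cell depletion set these shares, and the NK ratio was nearer to 1 in all alternatives tried (0.780 to 0.853), including 0.853 when 5 unnamed clusters with NK as their highest score were added (58.3% and 49.8%). With the 4 libraries clustered together, the T-like ratio was 0.697.

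**Figure D2:**
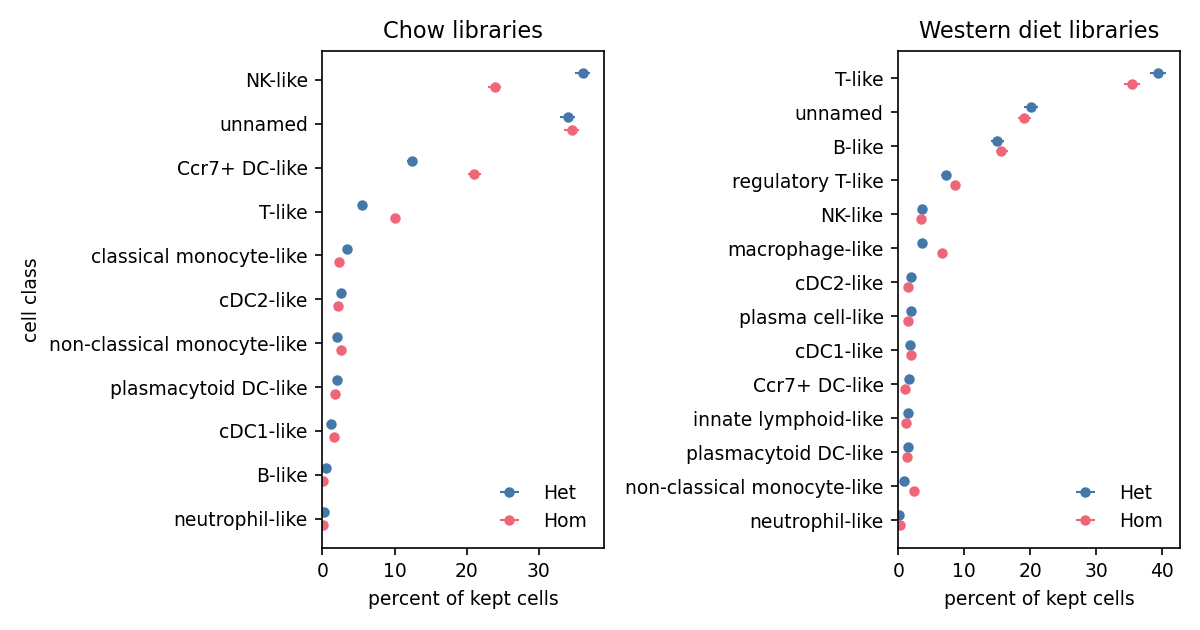
Share of cells per class (percent of kept cells) in the Het and Hom libraries of each setting, with exact binomial 95% intervals as bars, covering counting error only. NK-like cells took 36.1% and 23.9% of the chow libraries, and macrophage-like cells 3.67% and 6.64% of the western diet libraries.

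Within chow Ccr7+ DC-like cells, heat shock and AP-1 genes were higher in Hom and transcripts typical of NK cells were lower. Dnaja1, a co-chaperone of Hsp70, measured 403 CPM in Hom against 205 in Het, a ratio of 1.97 (1.84 to 2.09). Il1b, which encodes the inflammatory cytokine IL-1 beta, measured 78.8 against 43.9 CPM (1.80, 1.56 to 2.07). S100a4, a calcium-binding protein linked to cell motility, measured 452 against 811 CPM (0.556, 0.534 to 0.580).

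Heat shock and co-chaperone genes led the higher end. Cacybp, a chaperone-associated protein, was at 154 against 86.3 CPM, and Chordc1, an Hsp90-binding protein, at 105 against 60.5 CPM. The inducible Hsp70 gene Hspa1a was at 85.5 against 49.0 CPM, and Hsp90aa1, the inducible form of Hsp90, at 518 against 327 CPM. Nr4a3, a nuclear receptor induced by activation and linked to DC migration, measured 86.9 and 50.6 CPM. Of 23 measured stress response genes, 21 were higher, with a median log2 ratio of 0.33 at percentile 100, and Fos and Fosb, subunits of the AP-1 transcription factor, had ratios of 3.87 (2.93 to 5.18) and 4.40 (3.38 to 5.82). Other genes at the higher end were Mreg, a regulator of melanosome transport (201 against 132 CPM), Car2, a carbonic anhydrase (288 against 201 CPM), and Cpne8, a copine, which also led cluster 6 (78.5 against 50.5 CPM).

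All 8 NK cell markers were lower in Hom Ccr7+ DC-like cells, with a median of -0.63 at percentile 0. Gzma, a granzyme of cytotoxic granules, was at 151 against 286 CPM, Klrb1c, the NK1.1 receptor, at 40.9 against 79.1 CPM, and Ncr1, the activating receptor NKp46, at 68.6 against 127 CPM. Klrc2, another NK receptor gene, had a ratio of 0.405 (0.355 to 0.461), and Gzmb a ratio of 0.376 (0.326 to 0.432), with 245 of its 594 Het UMIs in 1 cell. Fam53b (0.473), the survival gene Bcl2 (0.523), the immunity-associated GTPase genes Gimap3 (0.456) and Gimap6 (0.515) and the protease inhibitor gene Serpina3g (0.520) were also lower. The NK marker median was -0.15 after thinning, -0.16 without doublet removal and -0.90 without cluster 23 and with double the doublets removed.

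Among lists tied to DC function, chemokine receptors had a median of -0.36 with 6 of 9 lower (percentile 0.280), and cholesterol synthesis genes a median of 0.10 with 13 of 19 higher (percentile 100), which median-of-ratios scaling put at 0.24. Cxcr6, the receptor for Cxcl16, had a ratio of 0.483 (0.384 to 0.606) and Ccr2, the receptor for monocyte-attracting chemokines, 0.748 (0.638 to 0.878). Cxcr6 also led an unnamed chow cluster with innate lymphoid and NK markers, and NK transcripts were lower in this class too. Ccr7, which guides DCs to lymph nodes, was at 1411 in Hom and 1389.6 CPM in Het (1.02, 0.988 to 1.04), and Ccl5, a ligand of Ccr5, at 8660.4 and 8508 CPM. Idi1, an isomerase of the sterol pathway and a leading gene of cluster 6, had a ratio of 1.24 (1.17 to 1.31), and Sqle, squalene epoxidase, 1.34 (1.06 to 1.69). Hmgcr, the rate-limiting enzyme of that pathway, had a ratio of 1.19 (1.06 to 1.33).

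Antigen presentation and maturation lists lay within the range of random lists in Ccr7+ DC-like cells. MHC class II genes had a median of -0.03 (6 higher, 7 lower, percentile 36.1), co-stimulation and maturation genes -0.12 (4 higher, 14 lower, percentile 5.05) and tolerance-linked genes -0.07 (5 higher, 7 lower, percentile 68.0). Ribosomal protein genes had a median of 0.12 with 69 of 81 higher. Median-of-ratios scaling moved the median gene of this class up by 0.17. That is more than these MHC, co-stimulation and tolerance medians, so they give no direction. The cholesterol synthesis median is also smaller than that shift. As the shift was upward, a median already above 0 was bound to stay there, so its sign under both scalings decides nothing. The chemokine receptor median was 0.00 with the class's clusters weighted equally, where Ccr2 was at 0.03, and Ccr2 was also above 0 after thinning (0.16) and with equal weight per cell (0.06). Cluster 9 held 29.6% of the class in Het and 16.0% in Hom, and cluster 6 held 32.2% and 39.4%.

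In chow NK-like cells, immediate-early and heat shock genes were higher in Hom, and the cytotoxic genes Gzma, Gzmb and Prf1 were lower. Fosb and Fos, AP-1 subunits, measured 209 against 31.3 CPM (6.68, 6.11 to 7.31) and 245 against 38.4 CPM (6.39, 5.89 to 6.93). Gzmb, the granzyme that activates caspases, measured 990 against 1624 CPM (0.610, 0.597 to 0.623). Cirbp, a cold-inducible RNA-binding protein, measured 67.4 against 116 CPM here (0.579, 0.535 to 0.627). Among genes open to naming with at least 50 CPM in both settings, it alone differed at least 1.5-fold in the same direction in NK-like cells.

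Of 23 stress response genes, 22 were higher in Hom NK-like cells, with a median of 0.79 at percentile 100. Jun and Junb, also AP-1 subunits, had ratios of 2.85 (2.71 to 2.99) and 1.88 (1.82 to 1.94). Hspa1b, an inducible Hsp70, was at 30.9 against 2.95 CPM, Klf4, a transcription factor of quiescence, at 36.2 against 6.47 CPM, and Hsph1, a nucleotide exchange factor of Hsp70, at 145 against 57.0 CPM. Dnaja1 (2.32), Chordc1 (1.75), the G-protein regulator Rgs2 (2.27) and Zfp36 (1.87), which destabilises cytokine mRNAs, were higher as well. Spp1, which encodes osteopontin and led cluster 2, had a ratio of 2.02 (1.86 to 2.20), and Nrgn, a calmodulin-binding protein that led an unnamed cluster, 1.82 (1.71 to 1.94).

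All 8 NK cell markers were lower in chow Hom NK-like cells, with a median of -0.27 at percentile 0.01, while T cell markers (0.17, 5 of 7 higher, percentile 99.645) and mitochondrial genes (0.20, 10 of 13 higher, percentile 99.82) were higher. Gzma was at 5568 against 7973 CPM, Klrb1c at 499 against 722 CPM and Prf1, the pore-forming perforin, at 710 against 949 CPM; Gzma, Gzmb and Prf1 led cluster 2. Tsc22d3 and Txnip, both glucocorticoid-responsive genes, had ratios of 0.654 and 0.684, Il18rap, a subunit of the IL-18 receptor, 0.689, Myc, a growth regulator, 0.673, and Coro2a 0.597. All 18 S phase genes were higher (median 0.27, percentile 100), with ratios of 1.83 (1.57 to 2.15) for Rrm2, a subunit of ribonucleotide reductase that led the cycling NK-like cluster, and 2.05 (1.67 to 2.52) for Uhrf1, which maintains DNA methylation. The cycling cluster held 1.49% of all kept cells in Het and 1.52% in Hom (1.02, 0.790 to 1.33), while the other NK-like clusters held smaller shares in Hom. MHC class II genes had a median of 0.24 (6 higher, 3 lower, percentile 100), with Cd74, the invariant chain, at 282 against 192 CPM.

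Interferon-stimulated genes had a median of 0.06 in chow NK-like cells (22 higher, 12 lower, percentile 100). Among the chemokines, Ccl3 had a ratio of 1.17 (1.11 to 1.24), Ccl4 0.823 (0.791 to 0.855) and Ccl5 0.796 (0.791 to 0.801), and their receptor Ccr5 was at 321 and 317 CPM. Ccr7 was at 20.1 against 5.49 CPM (3.65, 2.90 to 4.63). The interferon median was between -0.11 and -0.05 and Ccl4 was above 0 in log2 without doublet removal, with stricter cell filters, with the 4 libraries clustered together and with the unnamed NK-scoring clusters added; the S phase median was 0.01 and Uhrf1 at -0.09 with the 4 libraries together.

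Chow T-like cells showed the same stress genes higher in Hom, together with CD8 transcripts, while NK transcripts were lower. Fosb was at 166 against 26.0 CPM (6.39, 5.13 to 8.04), Fos at 177 against 39.2 CPM (4.53, 3.77 to 5.46) and Hsph1 at 182 against 47.8 CPM (3.80, 3.22 to 4.51). Of 24 stress response genes, 22 were higher (median 0.84, percentile 100), among them Hsp90aa1 (2.08), Jun (2.05) and Dnaja1 (2.02). Cd8b1 and Cd8a, the chains of the CD8 co-receptor, had ratios of 2.06 (1.93 to 2.20) and 2.07 (1.89 to 2.27), and the granzyme genes Gzmk and Gzmm 2.88 (2.31 to 3.61) and 2.31 (2.07 to 2.57). Cd8b1, Cd8a and Gzmm led one T-like cluster and Gzmk the other.

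Klrb1c had a ratio of 0.220 (0.188 to 0.257) in chow T-like cells, Gzma 0.289 (0.260 to 0.321), Ncr1 0.287 (0.244 to 0.337) and Fcer1g, a signalling adaptor of NK receptors, 0.291 (0.267 to 0.317). The 8 NK cell markers had a median of -0.56 (2 higher, 6 lower, percentile 0.01), and Cirbp a ratio of 0.499 (0.431 to 0.578). Interferon-stimulated genes (median 0.14, 24 of 31 higher) and S phase genes (0.23, 13 of 15 higher) were both at percentile 100. With the 4 libraries clustered together, the NK marker median was 1.22, and Klrb1c (1.23), Fcer1g (1.15), Ncr1 (2.07) and Gzma (0.15) were above 0 in log2. The interferon median was 0.04 after thinning and 0.83 with the 4 libraries together, where the S phase median was 0.04.

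**Figure D3:**
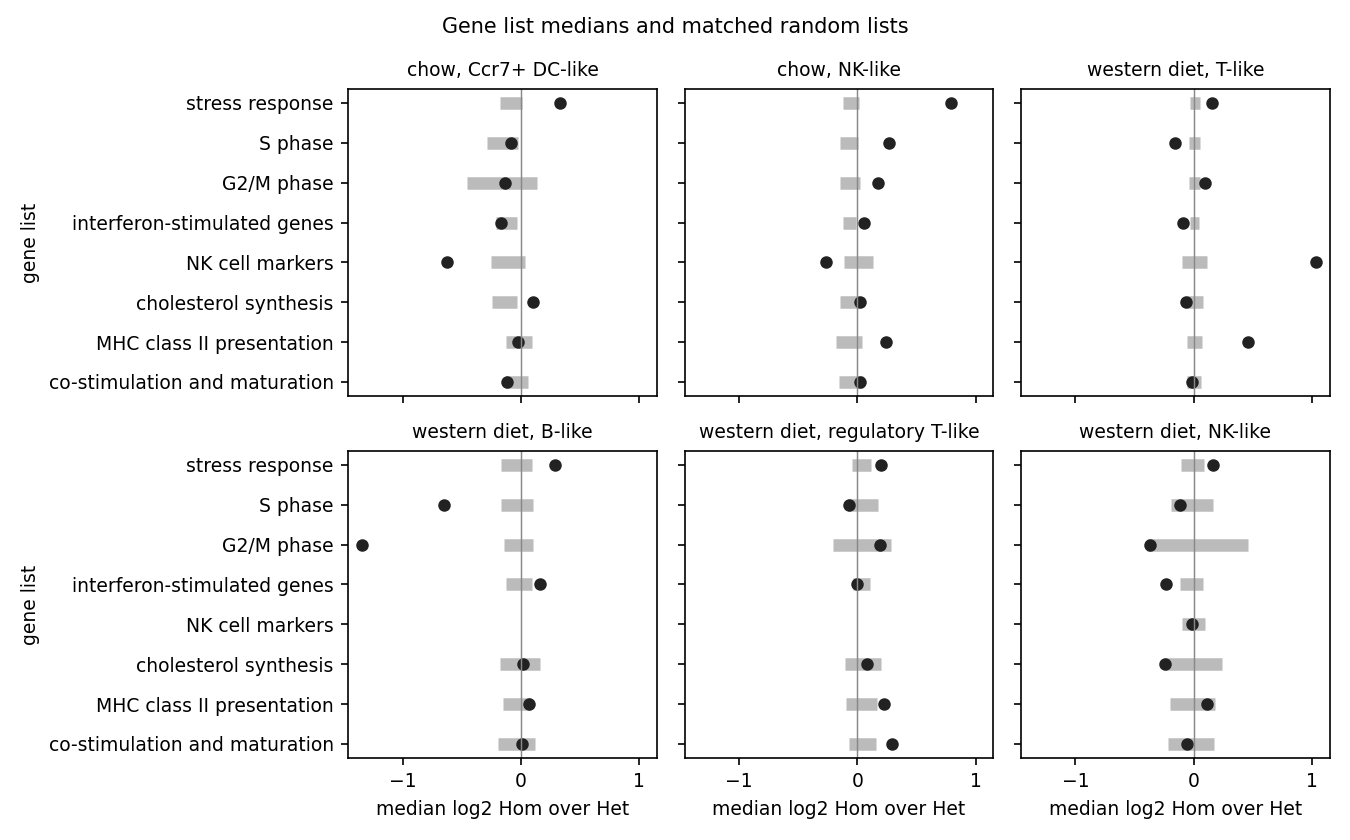
Median log2 ratio of Hom over Het for fixed gene lists (points), 1 panel per cell class, with grey bars for the central 95% of 10000 expression-matched random lists of the same size. Stress response genes lay above the random range in chow Ccr7+ DC-like (0.33) and NK-like cells (0.79), and cell cycle genes below it in western diet B-like cells.

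In the western diet pair, macrophage-like and non-classical monocyte-like cells took larger shares of the Hom library. Macrophage-like cells, tissue phagocytes, made up 3.67% of Het and 6.64% of Hom cells, a ratio of 1.81 (1.53 to 2.15). With no cell filter beyond 200 genes the ratio was 1.37, below that interval. An unnamed cluster led by macrophage genes such as Marco and C1qa, but with T cell as its highest score, did not differ. It held 7.69% of Het and 7.68% of Hom cells (0.998, 0.876 to 1.14). Non-classical monocyte-like cells, which patrol vessels, made up 0.861% and 2.44% (2.84, 2.05 to 3.98), and Ccr7+ DC-like cells 1.60% and 1.04% (0.649, 0.466 to 0.899). Neither of these shares was run under the alternatives. T-like cells made up 39.4% and 35.5% (0.901, 0.850 to 0.955), but the ratio was 0.991 among cells with Xist and no Y-linked UMI. Regulatory T-like cells, which express Foxp3 and restrain immune responses, made up 7.16% and 8.64% (1.21, 1.06 to 1.37), or 15.4% and 19.6% of T-like and regulatory T-like cells together.

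B-like cells made up 15.03% and 15.6% of the western diet libraries although CD19+ cells had been gated out, and NK-like cells 3.67% and 3.42%. The shares of cDC1-like cells were 1.70% and 1.98%, of cDC2-like cells 1.997% and 1.43%, of plasmacytoid DC-like cells 1.41% and 1.35%, of plasma cell-like cells 1.89% and 1.53% and of innate lymphoid-like cells 1.43% and 1.12%. Unnamed clusters held 20.1% and 19.1%. The nodes taken bear on these shares. The stated gate was CD19- MHC class II+, yet T-like cells, at 39.4% and 35.5%, were the largest class, so how far the gate shaped the shares is open.

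The sex-linked genes separated the western diet libraries. An Xist UMI without a Y-linked one was found in 69.4% of Het cells (4033 of 5810), although that library is labelled male, and in 50.3% of Hom cells (3198 of 6353). Only Y-linked UMIs were found in 1.51% of Het and 16.4% of Hom cells. In the chow libraries only Y-linked UMIs were found in 73.7% and 65.8% of cells and only Xist in 2 cells of each. Genotype and the share of male cells therefore differed together in the western diet pair. Values from cells with Xist and no Y-linked UMI are given where they were computed and differed. The shares of macrophage-like cells, with 6 Het and 4 Hom such cells, and of non-classical monocyte-like cells were not computed this way.

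**Figure D4:**
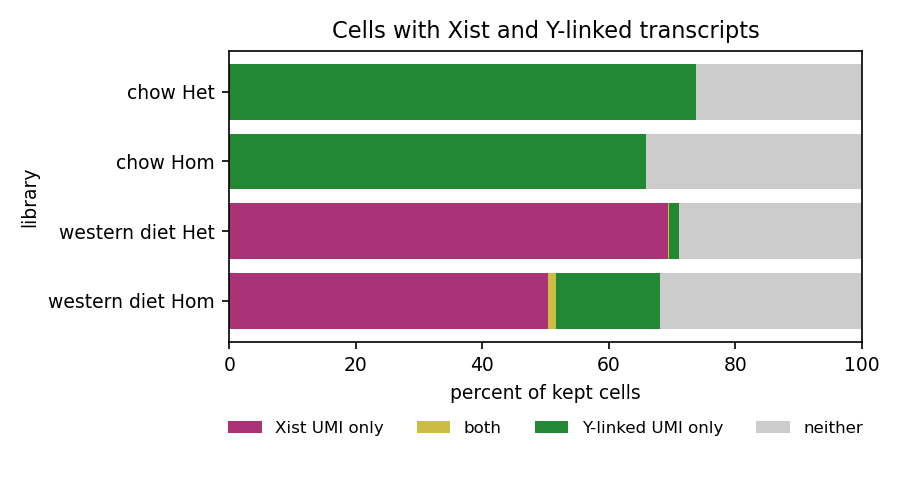
Share of kept cells (percent) with only Xist UMIs, both kinds, only Y-linked UMIs or neither in each of the 4 libraries, as stacked bars without intervals. Xist-only cells made up 69.4% of the western diet Het and 50.3% of the Hom library, against 2 cells in each chow library.

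In western diet T-like cells, interferon-stimulated and S phase genes were slightly lower in Hom. Ifit3 and Ifit1, antiviral genes induced by interferon, had ratios of 0.572 (0.521 to 0.628) and 0.669 (0.612 to 0.731), and Isg15, an interferon-induced ubiquitin-like protein, 0.771 (0.725 to 0.820). Of 33 interferon-stimulated genes, 25 were lower (median -0.09, percentile 0). These genes led a T-like cluster that held 3.85% of the class in Het and 1.91% in Hom. All 18 S phase genes were lower (median -0.16, percentile 0), with Hells, a chromatin remodeller, at 0.7998 (0.730 to 0.877) and Pcna, the sliding clamp of DNA replication, at 0.885 (0.824 to 0.9503).

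Markers of other cell types were higher in Hom T-like cells of the western diet pair. Cd74 (1.55), H2-Ab1 (1.72), a chain of MHC class II, and Lyz2 (1.496), the lysozyme of myeloid cells and a leading gene of the macrophage-like class, were higher, and MHC class II genes had a median of 0.46 (6 higher, 5 lower, percentile 100). S100a9 and S100a8, neutrophil calprotectin genes, had 4411 and 4287 UMIs in Hom against 0 and 1 in Het, of which 1 Hom cell held 4378 and 4266. Gzma was at 121 against 10.1 CPM, with 665 of 2002 Hom UMIs in 1 cell, and the NK cell marker list had a median of 1.03 (5 higher, 1 lower, percentile 100). Xist was lower (0.835, 0.807 to 0.864). Xcl1, a chemokine for cDC1 cells that led a cycling T-like cluster, had a ratio of 0.570 (0.538 to 0.603), with 913 of 3288 Het UMIs in 1 cell.

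Of the Ccr5 ligands in western diet T-like cells, Ccl3 had 252 UMIs in Het and 55 in Hom (0.213, 0.156 to 0.286), Ccl4 915 and 314 (0.334, 0.293 to 0.3803), with 320 of those in 1 Het cell, and Ccl5 a ratio of 0.822 (0.784 to 0.862). Ccr7, a leading gene of 1 T-like cluster, was at 98.9 and 99.3 CPM, and Ccr4, the Ccl17 receptor, at 11.7 CPM in Hom and 9.83 CPM in Het (1.19, 0.959 to 1.48). The stress response median was 0.15 (18 of 22 higher, percentile 100), with Jun at 1.20 (1.11 to 1.29). Without doublet removal Cd74 and H2-Ab1 were at -0.28 and -0.48 in log2, and with the 4 libraries clustered together Gzma was at -0.38, Cd74 at -0.07, H2-Ab1 at -0.05 and the NK marker median at -0.03. Among cells with Xist and no Y-linked UMI the interferon median was 0.00, and Hells was above 0 after thinning (0.16) and with equal weight per cell (0.01), where the S phase median was -0.04 and -0.02.

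In western diet B-like cells, cell division genes, Aicda and Mef2b were lower in Hom. Aicda, the deaminase of somatic hypermutation, measured 22.8 against 93.8 CPM (0.243, 0.192 to 0.306), and Mef2b, a germinal centre transcription factor, 25.5 against 84.8 CPM (0.301, 0.239 to 0.376). All 20 G2/M phase genes were lower (median -1.34, percentile 0), among them the proliferation marker Mki67 (0.265, 0.215 to 0.325), the survivin gene Birc5 (0.294) and Ube2c (0.275), a ubiquitin-conjugating enzyme of mitosis. All 18 S phase genes were lower too (median -0.65, percentile 0), with Tyms, thymidylate synthase, at 0.4003 (0.285 to 0.555) and the replicative helicase subunit Mcm6 at 0.464 (0.383 to 0.561).

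Klf2, Ccr7 and immediate-early genes were higher in Hom B-like cells. Klf2, a regulator of lymphocyte quiescence and trafficking, measured 711 against 485 CPM (1.47, 1.38 to 1.55), and Ccr7, which draws B cells to the T cell zone, 80.5 against 51.2 CPM (1.57, 1.31 to 1.89). Jun and Ier2, immediate-early genes, had ratios of 1.72 (1.55 to 1.91) and 1.61 (1.43 to 1.83), and the stress response list a median of 0.29 (20 of 23 higher, percentile 100). Stat4, a transducer of IL-12 signals, was at 1.82 (1.49 to 2.23) and S100a10, an annexin partner, at 1.47 (1.36 to 1.58). Stmn1, a microtubule regulator of dividing cells, was lower (0.332, 0.301 to 0.366), and oxidative phosphorylation genes had a median of -0.23 (31 of 33 lower, percentile 0.0500). Interferon-stimulated genes had a median of 0.16 (26 of 29 higher).

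Aicda and Mef2b led a B-like cluster that held 18.0% of the class in Het and 6.54% in Hom. Without that cluster the S phase median of B-like cells was -0.03. No G2/M median is given without that cluster or with the 4 libraries together. Lower G2/M genes are therefore not shown for the B-like cells outside it. With the 4 libraries clustered together the S phase median was 0.02 and Aicda (0.08), Mki67 (0.41), Birc5 (0.28), Ube2c (0.04), Stmn1 (0.09) and Mcm6 (0.13) were above 0 in log2, and among cells with Xist and no Y-linked UMI the G2/M and S phase medians were -2.07 and -1.03.

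In western diet regulatory T-like cells, the receptor genes Tnfrsf9 and Tnfrsf4 were higher in Hom, and Ccr8 was higher from few UMIs, with a difference that varied with thinning. Ccr8, a chemokine receptor of tissue regulatory T cells, had 16 UMIs in Het and 55 in Hom, or 6.97 and 17.6 CPM (2.52, 1.42 to 4.71). Tnfrsf9, the co-stimulatory receptor 4-1BB and a leading gene of this class, measured 265 against 185 CPM (1.43, 1.27 to 1.62), and Tnfrsf4, the receptor OX40 and another leading gene, 1143 against 832 CPM (1.37, 1.30 to 1.45). Of 13 co-stimulation and maturation genes, 11 were higher (median 0.30, percentile 99.98), among them Traf1, a signalling adaptor of such receptors (1.34, 1.18 to 1.53), but the median was -0.01 after thinning.

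A Ccr8 UMI was seen in 2.64% (11 of 416) of Het and 8.38% (46 of 549) of Hom regulatory T-like cells, at median depths of 4530.5 and 4797 UMIs. After thinning the shares were 1.98% (8 of 405) and 2.22% (12 of 541), with 11 and 8 cells left out, and the log2 ratio of Ccr8 was -0.00 in that draw, while the mean shares over all thinnings were 1.25% and 2.83%. In B-like cells, which should lack it, the shares were 0 of 873 (up to 0.344%) and 0 of 994 (up to 0.302%), at median depths of 3599 and 3807. Chemokine receptors as a list had a median of -0.17 (9 of 12 lower, percentile 0.570), with Ccr5 at 0.456 (0.259 to 0.788) from 37 and 23 UMIs, Ccr2 at 0.788 (0.632 to 0.982), Cxcr6 at 0.665 (0.420 to 1.05) and Ccr4 at 0.889 (0.594 to 1.34).

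Other genes higher in Hom regulatory T-like cells were Cd81, a tetraspanin (1.46, 1.28 to 1.66), Nrn1, which encodes neuritin and led a T-like cluster (1.49, 1.22 to 1.83), and Pglyrp1, a peptidoglycan recognition protein (1.46, 1.17 to 1.81). The myeloid gene Lyz2 (2.11, 1.87 to 2.38) and the MHC class II gene H2-Eb1 (1.54, 1.22 to 1.95) were higher too. Cd6, a T cell adhesion receptor, was lower (0.680, 0.587 to 0.787), as was Ccl5 (0.422, 0.379 to 0.470), with 246 of 945 Het UMIs in 1 cell. Of 283 Het UMIs of Xcl1, 280 came from 1 cell, and without the top cell of each library its log2 ratio was 0.13. The co-stimulation median was 0.15 with the 4 libraries clustered together, and among cells with Xist and no Y-linked UMI Xcl1 was at 1.14.

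Western diet NK-like cells (213 in Het and 217 in Hom) had lower interferon-stimulated genes in Hom and higher Ccr5 ligands. Of 34 interferon-stimulated genes, 25 were lower (median -0.23, percentile 0), with Ifit3 at 0.447 (0.325 to 0.609), Ifit1 at 0.349 (0.224 to 0.532) and Rtp4, an interferon-induced chaperone of receptors, at 0.582 (0.427 to 0.788). Ifi208, a member of the interferon-induced p200 family, was at 0.544 (0.405 to 0.728), while Isg15 was at 0.901 (0.731 to 1.11). Chemokine genes had a median of 0.34 (7 of 9 higher, percentile 99.965), with Ccl3 at 1.75 (1.54 to 2.001), Ccl4 at 1.26 (1.18 to 1.35) and Ccl5 at 1.11 (1.09 to 1.13).

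Fabp5, a fatty acid carrier, had 31 UMIs in Het and 136 in Hom NK-like cells of the western diet pair (3.83, 2.58 to 5.85), and Prf1 a ratio of 1.61 (1.42 to 1.84). Cirbp was lower, at 75.7 against 125 CPM (0.607, 0.473 to 0.777), as it was in the chow pair. Nrgn, a leading gene of the innate lymphoid-like class (0.474, 0.398 to 0.564), Prss2, a trypsin gene (0.446, 0.307 to 0.640), and Xist (0.464, 0.405 to 0.531) were also lower. NK cell markers had a median of -0.01 (4 higher, 4 lower, percentile 38.1), stress response genes 0.16 (17 of 22 higher, percentile 99.97) and macrophage markers 0.49 (5 of 6 higher). In cells with Xist and no Y-linked UMI, Ccl3 and Ccl4 were at -0.27 and -0.36 in log2, and the interferon median was -0.36.

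In western diet macrophage-like cells, Marco and Ccl12 were higher in Hom, while chemokine genes as a list had a median of -0.17 (5 higher, 7 lower, percentile 1.29). Marco, a scavenger receptor of sinus macrophages, had 66 UMIs in Het and 252 in Hom (1.70, 1.30 to 2.27), and Ccl12, a Ccr2 ligand, 92 and 370 (1.80, 1.43 to 2.28); both also led an unnamed cluster. Ccl6, a myeloid chemokine, and Ifi209, an interferon-induced p200 gene, were lower, at 0.368 (0.238 to 0.564) and 0.376 (0.251 to 0.562). Interferon-stimulated genes had a median of -0.21 (23 of 33 lower, percentile 0.0750). Mitochondrial genes were all higher (13 of 13, median 0.36, percentile 100), and 9 of 10 G2/M phase genes were higher (median 0.63), from few UMIs such as 6 and 31 for Birc5 and 9 and 40 for Ube2c.

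Ccl5 had a ratio of 0.199 (0.178 to 0.223) in macrophage-like cells, with 600 of 1009 Het UMIs in 1 cell, and Anxa1, an anti-inflammatory annexin, 3.099 (1.86 to 5.499), with 76 of 118 Hom UMIs in 1 cell. The class held 213 and 422 cells at median depths of 2309 and 2713.5 UMIs, with Y-linked UMIs only in 1 Het and 45 Hom cells. T cell markers were lower (7 of 8, median -0.38) and macrophage markers had a median of 0.12 (7 of 11 higher, percentile 93.1).

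Gene ratios of the chow and western diet pairs showed little agreement. Across 2400 genes of NK-like cells, Pearson's r was 0.140 and Spearman's rho 0.105, and 54.1% of genes had the same sign. Across 2056 genes of T-like cells, r was -0.144 and rho -0.0615, with 47.8% of the same sign. These correlations are across genes, which are not independent replicates, and the pairs shared no library. The r of T-like cells was 0.01 after thinning, and that of NK-like cells was between 0.03 and 0.14 over the alternatives.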

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

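The tests of genotype for the stress genes, of free Xist RNA and of pooled sexes were chosen after the results were seen. The other 4 tests were written before their own outcomes, but the doublet and damaged-cell tests drew on clusters and medians already seen. None of the differences between settings below was tested, as each setting had 1 library per genotype.

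Gene lists with opposite directions in the 2 settings stood out. Interferon-stimulated genes, the antiviral program, were higher in Hom in NK-like and T-like cells of the chow pair and lower in those of the western diet pair. Other western diet classes went both ways, with macrophage-like cells lower (-0.21) and B-like cells higher (0.16). Most members of the list were also higher in Hom in the small plasmacytoid DC-like and Ccr7+ DC-like classes of that pair, many from few UMIs. The interferon medians (chow minus western diet, log2 ratio of Hom over Het) differed by 0.29 in NK-like cells and 0.23 in T-like cells. In T-like cells, S phase genes differed by 0.39, although their chow median was 0.0361 with the 4 libraries clustered together and their western diet median -0.0378 after thinning and -0.0226 with equal weight per cell, and NK cell markers, receptors and granule genes, by -1.60. The interferon median of chow NK-like cells was -0.0548, -0.0773, -0.0777 and -0.106 under 4 alternatives, and that of western diet T-like cells was 0.00346 in Xist-only cells, so the opposite directions of this list depend on the processing. With the 4 libraries clustered together, the NK marker medians were 1.22 in chow and -0.03 in western diet T-like cells, the opposite order.

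Sex-linked transcripts gave a signal in the western diet libraries that the labels do not account for. Cells with an Xist UMI and no Y-linked UMI made up 69.4% of the Het library and 50.3% of the Hom library. Free Xist RNA in male cells would give cells with both kinds of UMI as often as chance pairs them, but in Hom they were 0.146 times as common (85 against 581), which argues against it. The Hom cells fell into 2 groups, and 24.5% of the cells with only 1 kind were Y-only, as pooled mice of both sexes would give. Whether the stated sex of the Het mice or the library label is wrong stays open.

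Stress response genes, heat shock proteins and AP-1 factors, were higher in Hom in the 3 large chow classes. Handling of the whole library predicted the same in unrelated classes, and the lowest median over 5 smaller chow classes was 0.46, so that explanation stays open. Damaged cells of high mitochondrial share are argued against as the source in NK-like cells, where the median at low mitochondrial share was 0.79. Damage to the preparation as a whole is not covered by that test. Cells of at least 10% mitochondrial UMIs, removed beforehand, made up 8.82% of deposited chow Hom and 3.95% of chow Het cells. An effect of genotype cannot be told apart from handling, since each genotype was 1 library. The lowest median over the western diet T-like, B-like, NK-like and regulatory T-like classes was 0.15. Macrophage-like cells were not among these classes, and western diet cDC1-like cells had -0.39. Stress during preparation of the chow Hom library may account for the pattern.

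NK transcripts were lower in chow Hom Ccr7+ DC-like cells. Doublets of NK cells and DCs as the whole cause would bring the median toward 0 as more of them were removed. Without the cluster that also held NK markers and with the doublet share doubled it was -0.90. Without doublet removal it was -0.16, so the median changed with the cells removed from each library, and the test cannot decide on doublets. Free RNA from NK cells as the whole cause would lower these transcripts in every class, but the ratio of their summed UMIs was 1.13 (1.04 to 1.22) in classical monocyte-like cells. The ratio was lower in the other 4 classes, at 0.429 (cDC2-like), 0.808 (plasmacytoid DC-like), 0.879 (non-classical monocyte-like) and 0.893 (cDC1-like), so a part from free RNA stays open. The median was -0.15 after thinning, -0.25 with equal weight per cell and -0.28 with equal weight per cluster. Its size therefore depends on the weighting as well as on doublet removal, and a difference in the DCs themselves may remain as a hypothesis.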

How the results depend on the processing

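The alternatives chosen after seeing the data were those without cluster 23, with equal weight per Ccr7+ DC cluster, with the unnamed NK-scoring clusters, with Xist-only western diet cells, without the Aicda-led or Ifit3-led cluster and without the top cell of a gene. The others were planned. Shares are ratios of Hom over Het, genes and lists are log2 ratios, and the cause of the shifts below was not tested.

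The class shares kept their value within the counting interval in 36 of 52 runs, 15 moved further and 1 reversed. Ccl17 did so in 7 of 8 runs and single genes in 1264 of 1566 (271 moved, 31 reversed). List medians have no counting interval: 147 of 211 lay closer to the reported median than the half-width of the matched random range, 54 moved further and 10 reversed. The r between settings stayed within its Fisher z interval across genes in 10 of 16 runs (5 moved, 1 reversed). Of 41 pairs of a focus gene and a class, 32 to 41 had the same sign over 9 runs (32 of the 37 that could be measured with stricter cell filters), and the pairs that reversed in a called direction are among the genes below. The count of named genes stayed within 1.5 times in 75 of 86 runs. The chow NK-like share moved in all 8 of its runs.

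Stricter cell filters (1000 genes, 5% mitochondrial) gave 0.853 for the chow NK-like share, Ccl4 0.14, S phase 0.19 and interferon genes -0.0548 in chow NK-like cells; stress 0.43, NK markers -0.21 and chemokine receptors -0.18 in chow Ccr7+ DC-like cells; interferon genes 0.23 and NK markers -0.33 in chow T-like cells. With no filter beyond 200 genes, the chow NK-like share was 0.780 and the western diet macrophage-like share 1.37.

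Without doublet removal, the chow NK-like share was 0.815, Ccl17 -2.94, Ccl4 0.12, S phase 0.16 and interferon genes -0.0773 in chow NK-like cells, NK markers -0.16 and chemokine receptors -0.0616 in chow Ccr7+ DC-like cells, NK markers -0.40 in chow T-like cells, and Cd74 -0.28 and H2-Ab1 -0.48 in western diet T-like cells. With double the doublets removed, the chow NK-like share was 0.814.

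Leiden 0.5 gave shares of 0.819 (chow NK-like), 0.831 (western diet T-like) and 1.19 (western diet B-like), and Leiden 2.0 gave 0.809 (chow NK-like). With the 4 libraries clustered together, shares were 0.837 (chow NK-like), 0.697 (chow T-like), 0.846 (western diet T-like) and 1.19 (western diet B-like). Of 24 named genes, 15 had the same sign in chow T-like, 15 in western diet T-like and 15 in western diet B-like cells. Chow NK-like cells then had Ccl4 0.14, Uhrf1 -0.0860, S phase 0.0144 and interferon genes -0.0777. Chow T-like cells had Klrb1c 1.23, Fcer1g 1.15, Ncr1 2.07, Gzma 0.15, stress 0.72, interferon genes 0.83, S phase 0.0361 and NK markers 1.22. Western diet T-like cells had Gzma -0.38, Cd74 -0.0703, H2-Ab1 -0.0531, interferon genes -0.25 and NK markers -0.0304. Western diet B-like cells had Aicda 0.0756, Mki67 0.41, Birc5 0.28, Ube2c 0.0419, Stmn1 0.0854, Mcm6 0.13 and S phase 0.0189, regulatory T-like cells co-stimulation 0.15, and the r between settings was 0.0723 (NK-like) and -0.0939 (T-like).

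Thinning to 2000 UMIs gave Ccr2 0.16, NK markers -0.15 and chemokine receptors -0.0932 in chow Ccr7+ DC-like cells, interferon genes 0.0372 in chow T-like cells, Hells 0.16, interferon genes -0.15, S phase -0.0378 and NK markers 0.29 in western diet T-like cells, interferon genes -0.11 in western diet NK-like cells, G2/M -1.05 and S phase -0.47 in western diet B-like cells, Ccr8 -0.00184 and co-stimulation -0.00688 in regulatory T-like cells, and r 0.0311 (NK-like) and 0.00758 (T-like). Equal weight per cell gave Ccr2 0.0552, NK markers -0.25 and chemokine receptors -0.13 in chow Ccr7+ DC-like cells, S phase 0.10 in chow T-like cells, Hells 0.0134, interferon genes -0.13, S phase -0.0226 and NK markers 0.28 in western diet T-like cells, and G2/M -0.95 and S phase -0.46 in western diet B-like cells.

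Median-of-ratios scaling gave stress 0.48, NK markers -0.46 and cholesterol synthesis 0.24 in chow Ccr7+ DC-like cells and interferon genes 0.23 in chow T-like cells. Without mitochondrial and ribosomal genes, stress was 0.86 in chow NK-like cells and NK markers 1.26 in western diet T-like cells. A pseudocount of 1 gave 0.89 and 1.69 for these, and G2/M -1.70 and S phase -0.81 in western diet B-like cells. With no list minimum, chemokine receptors were -0.0752 in chow Ccr7+ DC-like cells and NK markers 0.67 in western diet T-like cells. From genes of at least 10 CPM, r was 0.0678 (NK-like) and -0.0519 (T-like). With a named-gene minimum of 10 CPM, the shared named genes of 24 numbered 10 (chow Ccr7+ DC-like), 8 (chow NK-like), 12 (chow T-like), 6 (western diet T-like), 7 (B-like), 3 (regulatory T-like), 1 (NK-like) and 4 (macrophage-like), because the lower minimum admits low-count genes.

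Without cluster 23, NK markers were -0.41 in chow Ccr7+ DC-like cells, and with its clusters weighted equally Ccr2 was 0.0327, NK markers -0.28 and chemokine receptors 0.000605. With the NK-scoring unnamed clusters, the chow NK-like share was 0.853, Ccl4 0.16, S phase 0.13 and interferon genes -0.11. In Xist-only western diet cells, Xist was 0.0813, interferon genes 0.00346, S phase -0.10 and NK markers 0.57 in T-like cells, Ccl3 -0.27, Ccl4 -0.36 and interferon genes -0.36 in NK-like cells, G2/M -2.07 and S phase -1.03 in B-like cells, Xcl1 1.14 in regulatory T-like cells, and the shares 0.991 (T-like) and 1.41 (regulatory T-like). Without the Aicda-led cluster, S phase was -0.0348 in B-like cells, and without the top cell Xcl1 was 0.13 in regulatory T-like cells.

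Depth limits genes near the floor of 3 counts, such as Ccl17 in the western diet pair. List medians of the classes under 200 cells in a library were run under no alternative. Of the other list medians in the report without a value in this section, only NK cell markers in chow NK-like cells were run. Their median was between -0.27 and -0.21. The rest have no such check. No paired analysis across the settings was run, because each group was 1 library and the settings were read separately.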

Other observations

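Dendritic cell and monocyte classes under 200 cells in a library differed in genes that no comparison above covered, chosen for mention after their values were seen. In chow cDC1-like cells (95 Het and 136 Hom), the cross-presenting DCs, 19 of 20 cholesterol synthesis genes were higher in Hom (median log2 ratio 1.06, percentile 100 of matched random lists). Idi1, an isomerase of the pathway, had 13 and 95 UMIs (ratio 4.95, 2.76 to 9.63), Hmgcs1, the HMG-CoA synthase, 14 and 82 (3.97, 2.23 to 7.57), and Fdps, which makes farnesyl diphosphate, a ratio of 1.84 (1.40 to 2.45). MHC class II genes were lower there in 13 of 14 cases (median -0.24), with H2-Eb1, a beta chain, at 0.746 (0.723 to 0.771). In chow plasmacytoid DC-like cells (161 and 145), 7 of 7 chemokine genes were higher (median 2.18), with Xcl1, a ligand for cDC1 cells, at 8.62 (4.28 to 19.7) and Ccl5 at 6.37 (5.36 to 7.61), of which 1 Hom cell held 221 of 860 UMIs. Of 13 co-stimulation and maturation genes in the same class 10 were higher (median 0.75), and some genes also abundant in Ccr7+ DC-like cells were among the higher ones: Fscn1, an actin-bundling protein, had 15 and 203 UMIs (68 in 1 Hom cell), Ccr7 21 and 103, and Ccl22 1 and 46 (23 in 1 Hom cell). In chow classical monocyte-like cells (276 and 192), 12 of 12 chemokine genes were higher (median 0.54), with Cxcl2, a neutrophil attractant, at 13.2 (7.42 to 25.6) and Ccl2, a monocyte attractant, at 2.34 (1.90 to 2.89).

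MHC class II genes were lower in Hom non-classical monocyte-like cells of both settings, with 12 of 14 lower in the chow pair (median -0.46) and 12 of 13 in the western diet pair (median -0.48). H2-Ab1, a beta chain, had ratios of 0.662 (0.616 to 0.712) and 0.624 (0.585 to 0.666). In western diet plasmacytoid DC-like cells (82 and 86), 26 of 29 interferon-stimulated genes were higher in Hom (median 0.43, percentile 100), with Isg15, a ubiquitin-like protein, at 2.06 (1.54 to 2.76). In western diet cDC1-like cells (99 and 126), 13 of 15 co-stimulation and maturation genes were lower (median -0.68, percentile 0), with Icam1, an adhesion molecule of T cell contacts, at 0.513 (0.350 to 0.747). Single Het cells held 25 of 28 Het UMIs of Ccr7, 39 of 110 of Traf1 and 21 of 69 of Relb, but 6 of 73 of Icam1.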
